A study of Mus musculus with 12 samples.

How the data were processed

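RNA abundance was measured on 12 arrays of total RNA from the anterior striata of adolescent male Swiss CD-1 mice, an outbred stock. Per the labels, amplified cDNA was labelled with biotin by an Affymetrix whole-transcript kit, and 4 treatment groups of 3 arrays each were given saline, ethanol, mephedrone or mephedrone with ethanol. The last group is called the combination. Mephedrone is a synthetic cathinone, a stimulant drug. The labels do not say whether each array holds the RNA of a separate animal, and give no hour of collection, dose or array batch.

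The deposited table holds log2 values for 28853 probe sets, each centred on its median over the 12 arrays. The submitters' processing notes name RMA, a method that corrects background, normalises the arrays by quantiles and summarises probes, and the genome build mm8. The series design text names GeneSpring GX 7.3.1 for normalisation and analysis. Neither source describes the centring. It was checked on the table, where the median of every probe set over the 12 arrays is 0 within 7e-07. The log2 scale was also read from the deposited values, since no label states it. The values of 13408 probe sets (46.5%) step in units of 1 over 2 to the power 20, as single-precision numbers between 8 and 16 do. Those of 15429 (53.5%) step in units of 1 over 2 to the power 21, as numbers between 4 and 8 do. The step of the other 16 was not settled. The level of a probe set before centring is not in the table, so differences between arrays can be given but not signal over background, and small changes of dim probe sets may be compressed by background signal. No array was left out and there were 0 missing values. For arrays, the number of arrays limits the precision.

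Probe sets were given gene symbols from the platform annotation. Of all probe sets 21789 carried 1 symbol, 1621 carried several and 5443 were not listed there, and the single symbols named 19938 genes. All values were used as deposited, with no new normalisation. The choices that follow were made before the data were examined, except where stated. A filter on the lowest 30% by mean had been planned for a table of signal levels and was not used, since a centred table has no such mean.

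Group means were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), which gives a two-sided moderated test per probe set with 8 residual and 3.11 prior degrees of freedom. Adjusted p-values are those of Benjamini and Hochberg over 28853 probe sets, with a threshold of 0.05. The contrasts were each drug group against saline, the combination against mephedrone and against ethanol, the interaction, and the main effect of each drug. The interaction is the ethanol effect with mephedrone minus that without it, on the log2 scale. A main effect compares the mean of both groups given a drug with the mean of both groups not given it, 6 arrays against 6. A moderated F test asked for any difference among the 4 groups. Errors beside log2 changes are standard errors of that fit, and errors beside group means are SDs.

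Genes were named by a rule. Among probe sets past the threshold with 1 symbol and no overlap between the arrays compared, the rule took the 12 with the largest rise and the 12 with the largest fall. Where fewer than 10 passed in a direction, that direction was filled to 10 by the smallest unadjusted p among probe sets without overlap and with a change of at least 0.3, and these are stated not to have passed. By chance 10% of probe sets would lack overlap between 3 and 3 arrays, and 0.22% between 6 and 6. Lack of overlap between 3 and 3 arrays alone therefore says little about a gene. Symbols of receptor families, small RNAs and unnamed transcripts were counted but not named. Drd3 was always tested, because the series title names D3 receptors. The other genes named are members of the gene lists that passed or, per list, the 2 members with the smallest unadjusted p, with a few chosen after their values were seen, as stated. The rule asked for the probe set with the highest mean where a gene has several. A centred table cannot give it, so the other probe sets of several such genes are given beside the one named.

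The 37 gene lists, 18 of pathways and 19 of cell type markers, were fixed from textbook knowledge. Each was tested per contrast by camera in limma with a preset correlation of 0.01 between genes, with adjustment over the 37 lists. Camera with an estimated correlation and fry were run beside it. For lists each gene had 1 value, the mean of its probe sets, and members were adjusted over 19938 genes and over the list alone. The plan had named the probe set with the highest mean, which a centred table cannot give. The mean of the probe sets was therefore chosen after the table was seen. The list means of the arrays were also compared between 6 and 6 arrays by an exact two-sided permutation test over all 924 assignments. Correlations across arrays have permutation p-values from 1e+05 resamples.

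Alternatives were quantile normalisation, centring each array on its median, a trend and robust prior in eBayes, array quality weights, a block for the replicate number, 1 value per symbol, an unadjusted p under 0.05 with at least a 1.5-fold change, a fit to only the 6 arrays compared, and leaving out each array in turn. Added after the data were seen were a limit to probe sets at a level of 8 or more, leaving out both arrays that stand apart, and 2 composition scores as covariates, the first 2 principal components of the 19 cell type list means. The fit was tested on simulated data with 200 changed genes at each size. For 3 arrays against 3 it recovered 70.5% of log2 changes of 0.3 and 94.0% of 0.6. For 6 against 6 it recovered 88.0% and 98.5%. False calls numbered 35 and 38. The simulated probe sets varied independently, and more of them were changed than any main fit called. These shares therefore do not give the power in the real arrays, and a count of 0 does not show that such changes are absent. Scripts in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9) prepared the table and drew the figures. Gene positions were not analysed here.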

Results

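The study profiled RNA in the anterior striatum, a brain region central to reward, after a 10-day conditioned place preference procedure. In that procedure the animal learns to associate 1 compartment with a drug, here given 15 minutes before the animal was placed in it. Each of the 4 groups (saline, ethanol, mephedrone and their combination) had 3 arrays, and every array gave 28853 probe set values. The values are log2 differences from a probe set's median over the 12 arrays, so that a gene's level is relative and not absolute. The p-values measure the spread between these samples, which may be technical, because the labels do not say that they came from separate animals.

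The arrays differed in the levels of cell type markers. Whether they held different tissue was not tested apart from changes of expression within cells. Markers of the choroid plexus, the secretory tissue of the ventricles, had a list mean of 1.95 in combination replicate 3. The mean was 1.11 in saline replicate 2, 0.85 in ethanol replicate 1, 0.65 in combination replicate 2 and 0.64 in mephedrone replicate 1, and lay between -0.19 and -0.037 in the other arrays. In combination replicate 3 the means were also 0.74 for cortical excitatory neurons and 0.54 for oligodendrocytes, the myelin-forming cells, with -0.35 for pan-striatal projection neurons. Ethanol replicate 1 had 0.37 for hypothalamic and ventral forebrain neurons and -0.17 for pan-striatal projection neurons. These arrays also had the widest spread over all probe sets, with an SD of 0.169 in combination replicate 3 and 0.127 in ethanol replicate 1 against 0.068 to 0.102 in the others.

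**Figure D1:**
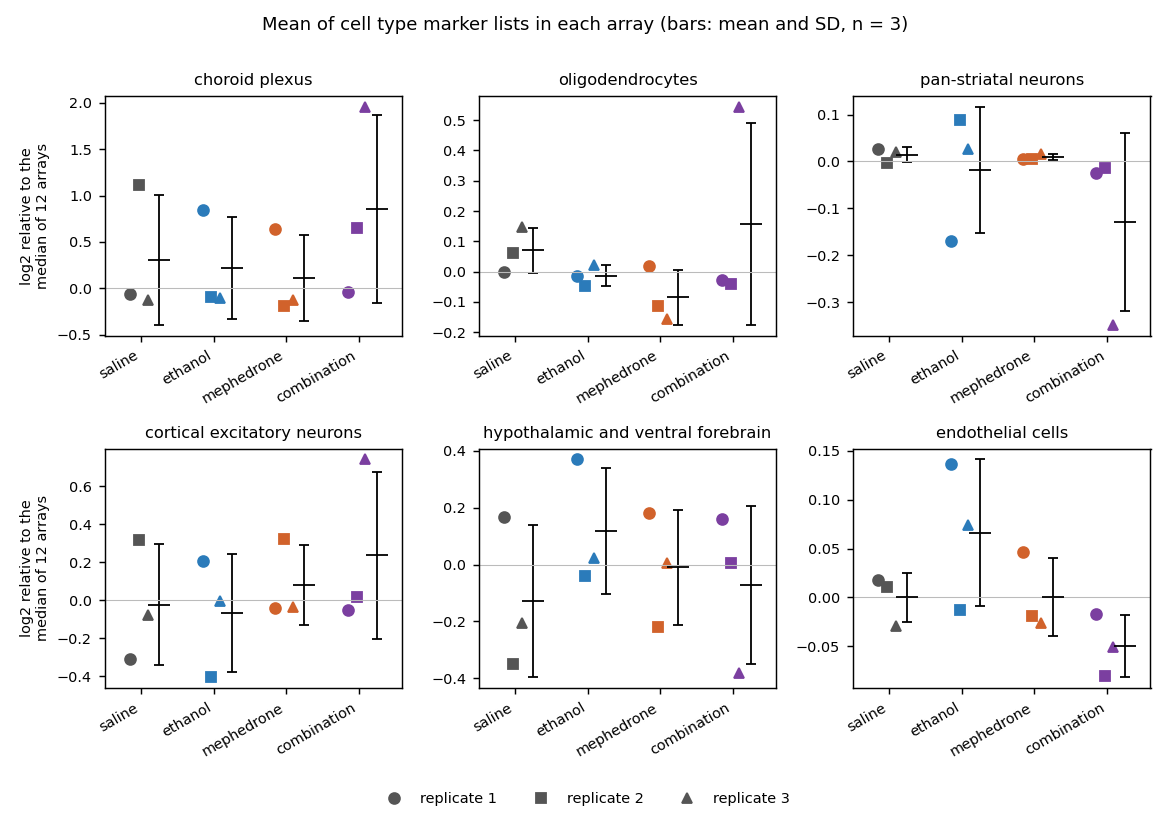
Mean log2 value of 6 cell type marker lists, relative to the median of 12 arrays (vertical axis), in each array of the 4 groups. Points are arrays and bars give the mean and SD of 3 arrays; combination replicate 3 has a choroid plexus mean of 1.95 and a pan-striatal mean of -0.35.

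The mephedrone main effect asked what differed between the 6 arrays given mephedrone, alone or with ethanol, and the 6 without it. Several transcripts of the circadian clock passed the test. Ciart, a repressor of the clock, rose by 0.75 in log2 (SE 0.060, 1.69-fold, adjusted p = 0.00188) and its other probe set by 0.73 (SE 0.086, adjusted p = 0.0127). Per3, a period gene, rose by 0.31 (SE 0.044, adjusted p = 0.0238), and Dbp, a clock-driven transcription factor, rose by 0.31 (SE 0.045, adjusted p = 0.0290). Arntl, which encodes the activator BMAL1, fell by 0.46 (SE 0.050, adjusted p = 0.0119). For each of these genes all 6 arrays lay on 1 side of all 6 others, as the naming rule required. Group means of Ciart over both probe sets were -0.35 ± 0.18 (SD, n = 3) with saline, -0.40 ± 0.098 with ethanol, 0.26 ± 0.11 with mephedrone and 0.47 ± 0.022 with the combination.

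**Figure D2:**
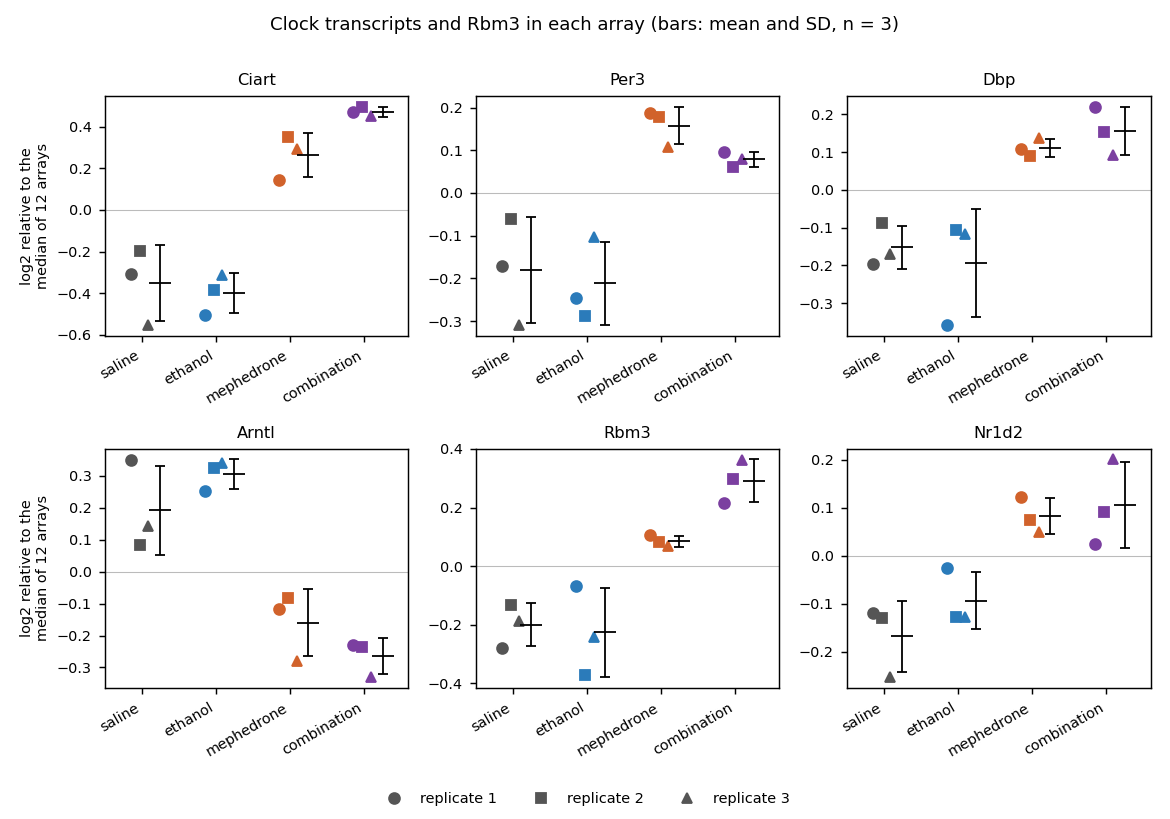
Log2 level relative to the median of 12 arrays (vertical axis) of Ciart, Per3, Dbp, Arntl, Rbm3 and Nr1d2 in each array of the 4 groups. Points are arrays and bars give the mean and SD of 3 arrays; the 6 arrays with mephedrone lie above the 6 without it for every gene drawn except Arntl, where they lie below.

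Of the 17 measured members of the circadian clock list, 12 were above and 5 below 0 in the mephedrone main effect, with a median of 0.14. Over all genes 3 passed as higher (Ciart, Per3, Dbp) and 1 as lower (Arntl), and adjusted over the list alone 9 passed as higher and 1 as lower. The list was called higher by camera (adjusted p = 9.75e-05) but not with an estimated correlation (adjusted p = 0.514 with an estimated correlation). By fry, which tests whether the genes of a list move on balance 1 way without comparing them with other genes, its adjusted p was 0.0179, the 1 list of 37 called so in this contrast. Fry also called 1 list in this way for the combination against saline. Asked for changes in either direction, fry called 8 lists in the mephedrone main effect. It so called 4 for the combination against saline, 3 for that against ethanol, and 1 each for mephedrone against saline and the interaction. An exact two-sided permutation test of the list mean, 6 arrays against 6, gave p = 0.00217, the smallest the 924 assignments can give. For 1 list at that limit, Benjamini-Hochberg adjustment over 37 lists gives 0.0801, so it could not pass alone. Nr1d2, a repressor of Arntl, rose by 0.23 (SE 0.038, adjusted p = 0.0461 over all probe sets), and its adjusted p was 0.0598 with 1 value per gene. Nr1d2 was chosen after its value was seen.

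Beyond the clock, Rbm3, an RNA-binding protein known for its induction by mild cold, rose on all 3 of its probe sets, by 0.42, 0.39 and 0.39 (SE 0.049, 0.050 and 0.049, largest adjusted p = 0.0136). The probe sets of Rbm3 and of Ciart may read near-identical copies, and were not taken as independent. Trhr2, a receptor for thyrotropin-releasing hormone, rose by 0.32 (SE 0.044, adjusted p = 0.0238). Sdhaf4, an assembly factor of succinate dehydrogenase, rose by 0.35, and the other Sdhaf4 probe set, at 0.12, did not pass. Hhipl1 rose by 0.27, Pex7, which imports proteins into peroxisomes, by 0.26 and Coq3, an enzyme of ubiquinone synthesis, by 0.25. Cldn5, the tight junction protein of brain endothelium, fell by 0.30 (SE 0.044, adjusted p = 0.0292). Dio2, which activates thyroid hormone, fell by 0.29 and Trim9, a neuronal ubiquitin ligase, by 0.27. Falls were also called for Fam135b (0.25), Cacng2 (0.25), a partner of AMPA receptors, Dhrs3 (0.19), Mpp3 (0.19) and Zfp365 (0.16). Fam135b had 5 probe sets, of which 1 passed, and Cacng2 had 2, of which 1 passed, all below 0. Nfu1, an iron-sulphur cluster protein, also rose, by 0.55, with overlap between the arrays and 0.14 on its other probe set, which did not pass.

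In all, 68 probe sets passed in limma for the mephedrone main effect, 36 higher and 32 lower, for 39 single symbols. The balance of directions moved with the setting: 226 higher and 124 lower with array quality weights, 105 and 42 without both arrays that stand apart, 73 and 41 without ethanol replicate 1, 18 and 8 without saline replicate 2, 7 and 13 with a replicate block, and 18 and 29 without saline replicate 1. At an unadjusted p under 0.05 in limma with at least a 1.5-fold change, 9 were higher and 28 lower. Of the 68 called probe sets, 23 had no single symbol, 19 of them lower, and 4 were copies of A530040E14Rik, at -0.38 each. Leaving out 1 array moved the count to between 10 and 114. It was 10 without mephedrone replicate 1, 14 without ethanol replicate 3, 18 without mephedrone replicate 2 or combination replicate 1, 19 without mephedrone replicate 3, 22 without ethanol replicate 2, 26 without saline replicate 2 and 114 without ethanol replicate 1. With a replicate block it was 20, with array quality weights 350, with quantile normalisation 45, with 1 value per symbol 23, and without both arrays that stand apart 147. Among the genes named by the rule, Arntl, Pex7, 1 probe set of Ciart and 1 of Rbm3 kept their calls in all 20 settings tried, and each of the others lost its call in at least 1. Nfu1 and Nr1d2, named outside the rule for this contrast, were not followed over those settings.

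Activity-regulated immediate early genes, which neurons induce within minutes of firing, had a median of -0.18 in the mephedrone main effect, with 20 of 27 members below 0. None passed over all genes in limma, and 15 passed as lower and 1 as higher adjusted over the list alone. Camera called the list lower (adjusted p = 4.97e-09), but not with an estimated correlation (adjusted p = 0.549 with an estimated correlation). Values were -0.27 for Egr3 (SE 0.049), -0.78 for Nr4a1 (SE 0.158), -0.64 for Egr2 (SE 0.145) and -0.53 for Arc (SE 0.120), and Nr4a2 was the member in the other direction at 0.75 (SE 0.271). The exact two-sided permutation test of the list mean gave p = 0.0238, and 0.260 after adjustment. The list means of the arrays were 0.23, -0.080 and 0.008 with saline, 0.21, 0.21 and 0.18 with ethanol, -0.091, -0.011 and 0.050 with mephedrone and -0.090, -0.055 and -0.092 with the combination.

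**Figure D3:**
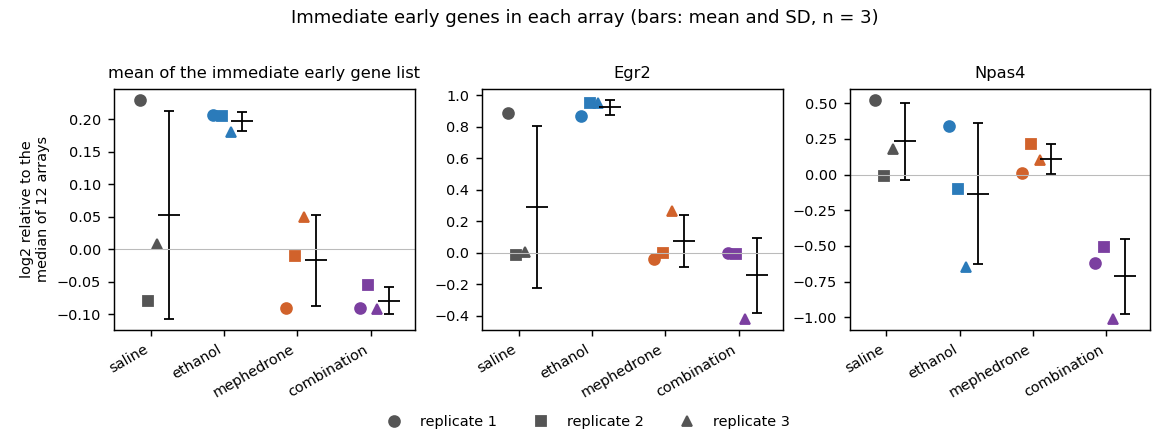
Log2 level relative to the median of 12 arrays (vertical axis) of the immediate early gene list mean, Egr2 and Npas4 in each array of the 4 groups. Points are arrays and bars give the mean and SD of 3 arrays; the 3 ethanol arrays have list means of 0.18 to 0.21 and the 3 combination arrays -0.092 to -0.055.

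Endothelial markers had a median of -0.068 in the mephedrone main effect, with Cldn5 the 1 of 13 members past the test over all genes and 6 lower adjusted over the list alone. Microglial markers, of the resident immune cells, had a median of -0.077 with 12 of 13 below 0 and none past either test, the lowest p being for Siglech (-0.14) and C1qa (-0.11). Camera called both lists lower (adjusted p = 2.55e-04 and 9.24e-04), and neither with an estimated correlation (adjusted p = 0.549 with an estimated correlation for both). It also called glucocorticoid-responsive genes (median 0.063), sterol and fatty acid synthesis (0.069) and oxidative phosphorylation (0.027) higher and cytosolic ribosomal proteins (-0.027) lower, with adjusted p from 0.0196 to 0.0408 (adjusted p = 0.794 with an estimated correlation for all 4). Those 4 calls ended without combination replicate 3, when the list means were 0.053, 0.031, 0.018 and -0.016, against 0.077, 0.073, 0.027 and -0.021 in all arrays. The glucocorticoid call also ended without saline replicate 3 (0.064) or ethanol replicate 1 (0.078), and the sterol call without saline replicate 1 (0.067), ethanol replicate 2 (0.048) or mephedrone replicate 1 (0.063). The oxidative call ended without saline replicate 2 (0.021), ethanol replicate 2 (0.020) or 3 (0.015) or mephedrone replicate 1 (0.022), and the ribosomal call without saline replicate 3 (-0.019), ethanol replicate 1 (-0.004) or mephedrone replicate 2 (-0.017). While still called, the oxidative mean was 0.046 without ethanol replicate 1 and the ribosomal mean -0.037 without ethanol replicate 3.

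The combination against ethanol asked what mephedrone added to ethanol. Ciart rose by 0.90 and 0.84 on its probe sets (SE 0.121 and 0.085, adjusted p = 0.0459 and 0.0206). Rbm3 rose by 0.54, 0.51 and 0.50 (SE 0.069, 0.070 and 0.069, adjusted p = 0.0459), and Arntl fell by 0.57 (SE 0.070, adjusted p = 0.0459). C4b, a complement component, rose by 0.36 (SE 0.048), Lsm4, an RNA-processing factor, rose by 0.24 (SE 0.031) and Mpp3, a scaffold protein, fell by 0.27 (SE 0.037), each with adjusted p = 0.0459. In each of these genes the 3 combination arrays lay on 1 side of the 3 ethanol arrays, as the naming rule required. Group means of Lsm4 were 0.030 with saline, -0.19 with ethanol, -0.022 with mephedrone and 0.050 with the combination. In the same order those of Mpp3 were 0.017, 0.21, -0.088 and -0.057, and those of C4b 0.035, -0.13, -0.006 and 0.23. The ethanol mean thus lay apart from that of saline in Lsm4, Mpp3 and C4b, though no probe set passed for ethanol against saline. The combination mean lay near that of saline in Lsm4. Genes that did not pass included Cirbp, a cold-inducible RNA-binding protein, at 0.38 (SE 0.077), Dbp at 0.35, Trhr2 at 0.38, Cldn5 at -0.41 (SE 0.062), Dusp6 at -0.36, Dio2 at -0.38, Egr2 at -1.07 (SE 0.207), Vgf at -0.56 and Pld5 at -0.68.

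Here 10 probe sets passed, 7 higher and 3 lower, including 1 without a symbol, and 8 of the 10 were also called in the mephedrone main effect. The count was 0 without any 1 of the combination arrays, ethanol replicate 2, ethanol replicate 3 or mephedrone replicate 2. It was 1 without mephedrone replicate 1 or 3, 2 without saline replicate 3, 4 without saline replicate 2, 5 without ethanol replicate 1 and 17 (6 higher and 11 lower) without saline replicate 1. It was also 0 with quantile normalisation, a replicate block, only the 6 arrays compared, or composition covariates, and 4 without both arrays that stand apart. At an unadjusted p under 0.05 in limma with at least a 1.5-fold change, 10 probe sets were higher and 54 lower.

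Immediate early genes were the list with the smallest p in the combination against ethanol (median -0.30, 21 of 27 below 0, adjusted p = 2.16e-11). None passed over all genes in limma, and 16 passed as lower and 1 as higher adjusted over the list alone, with Dusp6 at -0.36 (SE 0.057) and Nr4a1 at -1.16 (SE 0.223). Endothelial markers had a median of -0.13 (adjusted p = 3.85e-07), with none past the test over all genes and 7 of 13 lower adjusted over the list alone, including Cldn5 and Tek, an endothelial receptor, at -0.22. The circadian clock list had a median of 0.12 (adjusted p = 0.00105), with 1 higher and 1 lower over all genes and 8 higher and 1 lower adjusted over the list alone. All 3 calls were lost with an estimated correlation (adjusted p = 0.352 with an estimated correlation for each). Of the 12 other lists called, oligodendrocytes (0.17), choroid plexus (0.55), cortical excitatory neurons (0.24) and pan-striatal neurons (-0.12) had list means of 0.17, 0.64, 0.30 and -0.11 in all arrays. Without combination replicate 3 these were -0.021, 0.087, 0.051 and -0.002, which ended each call (adjusted p = 0.677 with an estimated correlation for each in all arrays). Leaving out ethanol replicate 2 also ended the calls of choroid plexus (0.48), cortical (0.14) and pan-striatal markers (-0.058), and ethanol replicate 3 that of pan-striatal markers (-0.089). Microglial markers had a median of -0.10 and heat shock genes -0.058 (both adjusted p = 0.677 with an estimated correlation), with list means of -0.089 and -0.085. Their calls were lost without combination replicate 2 (microglial list mean -0.061) and ethanol replicate 1 (heat shock list mean -0.062). The other 6 lists were glucocorticoid-responsive genes (list mean 0.073), oxidative phosphorylation (0.036), sterol synthesis (0.11) and ependymal markers (0.078), called higher, and cholinergic (-0.23) and ventral forebrain markers (-0.19), called lower. None was called with an estimated correlation (adjusted p = 0.796 with an estimated correlation for ventral forebrain markers and 0.677 for the others). Without combination replicate 3 their means were 0.024, 0.019, 0.028, 0.054, -0.11 and -0.034, and each call ended. The glucocorticoid call also ended without saline replicate 1 or 3 (0.073 each), ethanol replicate 1 (0.075) or 3 (0.070) or combination replicate 1 (0.081), and the oxidative call without ethanol replicate 2 (0.022) or 3 (0.012). The sterol call ended without ethanol replicate 2 (0.061), the ependymal call without ethanol replicate 2 (0.067) or 3 (0.061) or combination replicate 2 (0.082), and the ventral forebrain call without ethanol replicate 1 (-0.063). While still called, the cholinergic and ventral forebrain means were -0.35 and -0.31 without combination replicate 1, the oxidative and sterol means 0.074 and 0.17 without ethanol replicate 1, and the glucocorticoid mean 0.12 without combination replicate 2. Choroid plexus markers, still called, had a mean of 1.08 without combination replicate 1, and oligodendrocytes had 0.27 without combination replicate 1 or 2. Pan-striatal markers had -0.19 without ethanol replicate 1 and -0.17 without combination replicate 2.

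The comparison of mephedrone with saline asked for the effect of mephedrone alone, and no probe set passed in limma (0 of 28853, with 2154 at an unadjusted p under 0.05 and 1443 expected by chance). Among values without overlap the smallest p-values were those of Nfu1 at 0.79 (SE 0.097) and Ciart at 0.66 (SE 0.085), both with adjusted p = 0.0755. Their other probe sets had 0.14 for Nfu1 (SE 0.083, adjusted p = 0.764) and 0.57 for Ciart (SE 0.121, adjusted p = 0.311). Per3 had 0.34 (SE 0.062, adjusted p = 0.258), Gpx6, a glutathione peroxidase, 0.69 (SE 0.145, adjusted p = 0.311), and Arntl -0.35 (SE 0.070, adjusted p = 0.307). Of the 10 lowest named, 8 were copies of Srsy, a multi-copy Y-linked transcript, at -0.55 to -0.39, and none passed. Over those 8 probe sets the values were -0.39 to -0.25 without saline replicate 2 and -0.75 to -0.54 without saline replicate 1. The count was 9 without ethanol replicate 1, 1 without combination replicate 1, 3 with quantile normalisation, 8 with array quality weights, 1 with only the 6 arrays compared and 14 without both arrays that stand apart.

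The circadian clock list had a median of 0.15 against saline, with 13 of 17 members above 0, 0 past the test over all genes, and 7 higher and 1 lower adjusted over the list alone (adjusted p = 1.74e-04; adjusted p = 0.585 with an estimated correlation). Oligodendrocyte markers had a median of -0.17 with 15 of 15 below 0 and none past either test, the lowest p being for Mobp (-0.20) and Cnp (-0.19). Meningeal and fibroblast markers had a median of -0.11, thalamic markers -0.082 and microglial markers -0.053, all called lower (adjusted p = 0.872 with an estimated correlation for these 4). In all arrays the list means were -0.11 for meningeal, -0.056 for thalamic and -0.054 for microglial markers. Without saline replicate 2 the meningeal list mean was -0.003 and its call ended, and without saline replicate 3 it was -0.17, still called. The thalamic mean was -0.089 without saline replicate 3 and -0.11 without mephedrone replicate 1, still called. The thalamic call also ended without saline replicate 1 (-0.032) or 2 (-0.047), ethanol replicate 3 (-0.056) and mephedrone replicate 2 (-0.039) or 3 (-0.022), and the microglial call without saline replicate 1 (-0.018) or mephedrone replicate 3 (-0.041). Immediate early genes had a median of -0.048 and ribosomal protein genes -0.047, both called lower (adjusted p = 0.95 and 0.937 with an estimated correlation). The immediate early list mean, -0.070 in all arrays, was 0.018 without saline replicate 1 and -0.033 without mephedrone replicate 1. The ribosomal mean, -0.032 in all arrays, was -0.022 without mephedrone replicate 2. Each of these ended the call. Without saline replicate 2 the immediate early list mean was -0.14, still called.

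The combination against saline asked for the effect of both drugs together. Ciart rose by 0.89 (SE 0.085, 1.85-fold, adjusted p = 0.0123) and was the 1 gene to pass. It was higher in 3 of 3 arrays than in any saline array, as the naming rule required. Its other probe set, at 0.76 (SE 0.121, adjusted p = 0.0763), did not pass. Genes that did not pass were Rbm3 at 0.52, 0.49 and 0.46, Nfu1 at 0.68 with 0.15 on its other probe set (adjusted p = 0.464), Cmc1 at 0.35 (SE 0.042, adjusted p = 0.0551), Dld, a mitochondrial dehydrogenase subunit, at 0.33 and Zfp566 at 0.49. On the lower side, not passed, were Arntl at -0.46 (adjusted p = 0.0660), Cldn5 at -0.39, Egr3 at -0.32, Thrb, a thyroid hormone receptor, at -0.31 and Npas4, an activity-induced transcription factor, at -0.95 (SE 0.220, adjusted p = 0.121). The count of 1 became 49 (9 higher and 40 lower) without combination replicate 2, and 17 (10 and 7) without ethanol replicate 1. It became 16 (2 and 14) without saline replicate 1, 11 (7 and 4) without ethanol replicate 2 and 3 (3 and 0) without saline replicate 3. It was 0 without saline replicate 2, combination replicate 1 or combination replicate 3, with quantile normalisation, a replicate block or only the 6 arrays compared, and 12 without both arrays that stand apart. The called Ciart probe set kept its call in 14 of 20 settings. At an unadjusted p under 0.05 in limma with at least a 1.5-fold change, 11 probe sets were higher and 59 lower.

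In that comparison 13 of 17 clock genes were above 0 (median 0.17), with 1 higher over all genes and 8 higher and 1 lower adjusted over the list alone (adjusted p = 2.46e-04). Oxidative phosphorylation genes had a median of 0.071 with 32 of 41 above 0, none past the test over all genes, and 8 higher and 1 lower adjusted over the list alone, with Ndufs1 at 0.29 (SE 0.045) and Uqcrc2 at 0.16. Glucocorticoid-responsive genes had a median of 0.092 with 2 of 19 higher adjusted over the list alone, Tsc22d3 at 0.35 (SE 0.084) and Nfkbia at 0.30, and none over all genes. Immediate early genes had -0.11, with 2 of 27 lower adjusted over the list alone (Egr3, Npas4), and endothelial markers -0.061 with 4 of 13, and none of either over all genes. Sterol and fatty acid synthesis had 0.16 with Fdft1 at 0.26 the 1 member higher over the list alone, alcohol and aldehyde metabolism 0.051, pan-striatal neurons -0.14, potassium and sodium channels -0.056 and ribosomal proteins -0.042. Camera called all 10 lists with the preset correlation and none with an estimated one (adjusted p = 0.609 with an estimated correlation for each). In all arrays the list means were -0.13 for immediate early genes, 0.15 for sterol synthesis, 0.097 for alcohol metabolism, -0.14 for pan-striatal markers, -0.038 for channels and 0.13 for glucocorticoid-responsive genes. The list mean of immediate early genes was -0.043 without saline replicate 1, and those of sterol synthesis 0.069, alcohol metabolism 0.048, pan-striatal markers -0.035 and channels -0.020 without combination replicate 3, each ending the call. Saline replicate 1 also ended the calls of alcohol metabolism (0.094) and channels (-0.023), and saline replicate 2 that of channels (-0.042). The glucocorticoid list kept its call without combination replicate 3, at a mean of 0.080.

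The comparison of ethanol with saline asked for the effect of ethanol alone. No probe set passed in limma (0 of 28853, with 1440 at an unadjusted p under 0.05 and 1443 expected by chance), and 1 passed without saline replicate 1. Without overlap, 1518 probe sets lay higher and 954 lower, where 10% of all probe sets would lack overlap by chance. Values without overlap that did not pass were 0.48 for Bcl6, a transcriptional repressor (SE 0.10, adjusted p = 0.992), 0.31 for Fos, an immediate early gene (SE 0.105), 0.33 for Cartpt, a striatal neuropeptide (SE 0.129), and -1.02 for Gh, growth hormone (SE 0.485). Without saline replicate 2 Fos had 0.18, and without saline replicate 3 Gh had -0.67. Heat shock and unfolded protein response genes had a median of 0.12, with 23 of 25 above 0, none past either test and Dnajb11 at 0.26 and Hspd1 at 0.18 (adjusted p = 1.99e-06). Immediate early genes had a median of 0.13, with 20 of 27 above 0, none past the test over all genes and 1, Dusp6 at 0.28 (SE 0.057), higher adjusted over the list alone. Ribosomal protein genes had -0.028, with 27 of 39 below 0. Markers of ventral forebrain (0.25), cholinergic neurons (0.12), astrocytes (0.078) and endothelium (0.049) were called higher, and those of oligodendrocytes (-0.056) lower. None of these 8 calls held with an estimated correlation (adjusted p = 0.947 with an estimated correlation for each). In all arrays the list means were 0.25 for ventral forebrain, 0.22 for cholinergic, 0.099 for astrocyte, 0.066 for endothelial and -0.084 for oligodendrocyte markers, 0.14 for immediate early genes and -0.038 for ribosomal genes. Without ethanol replicate 1 the list means of ventral forebrain, cholinergic, astrocyte and endothelial markers were 0.12, 0.16, 0.053 and 0.030, and each call ended. Without saline replicate 2 the immediate early, ventral forebrain, cholinergic and astrocyte list means were 0.078, 0.14, 0.15 and 0.046. The call of ribosomal genes ended without ethanol replicate 3 (-0.006), and those of oligodendrocyte and endothelial markers without saline replicate 3 (-0.045 and 0.051), all likewise lost. Oligodendrocyte markers also lost their call without ethanol replicate 2 (-0.067), endothelial markers without ethanol replicate 3 (0.062) and ventral forebrain markers without saline replicate 3 (0.21). Astrocyte markers lost theirs without saline replicate 3 (0.10), mephedrone replicate 1 or 2 or combination replicate 1 (0.099 each), and cholinergic markers without saline replicate 3 (0.20), ethanol replicate 2 (0.21), mephedrone replicate 2 or 3 or combination replicate 2 (0.22 each). Among means still called, without saline replicate 1 immediate early genes had 0.23 and ventral forebrain markers 0.39, without ethanol replicate 1 ribosomal genes had -0.073, and without ethanol replicate 2 endothelial markers had 0.11.

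The combination against mephedrone asked what ethanol added to mephedrone. No probe set passed in limma (0 of 28853, with 1062 at an unadjusted p under 0.05 and a smallest adjusted p of 0.988), and 1 passed without combination replicate 2. Values without overlap that did not pass were 0.57 for Gfap, the astrocyte filament protein (SE 0.202), 0.42 for Aldh1a1, an aldehyde dehydrogenase (SE 0.164), -0.69 for Gpx6 (SE 0.145), -0.82 for Npas4 (SE 0.220), -0.30 for Thrb (SE 0.075) and -1.21 for Gh (SE 0.485). Without combination replicate 3 Gfap had 0.27 and Aldh1a1 0.21, and without mephedrone replicate 3 Gh had -0.55. Camera called 14 lists with the preset correlation and 0 with an estimated one (smallest adjusted p = 0.523 with an estimated correlation). The markers of choroid plexus (median 0.62), oligodendrocytes (0.24), oligodendrocyte precursors (0.090), ependyma (0.066) and astrocytes (0.059) were called higher. Those of pan-striatal neurons (-0.13), D1-type projection neurons (-0.099) and endothelium (-0.042) were called lower, and none of these lists had a member past the test over all genes. Sterol synthesis (0.11), synaptic vesicle release (0.052), oxidative phosphorylation (0.042) and alcohol metabolism (0.036) were called higher and immediate early genes (-0.062) and glutamate signalling (-0.009) lower. In all arrays the list means were 0.75 for choroid plexus, 0.24 for oligodendrocytes, 0.10 for oligodendrocyte precursors, 0.12 for astrocytes, 0.088 for ependyma, -0.14 for pan-striatal neurons, -0.12 for D1-type neurons and -0.050 for endothelium. They were 0.12 for sterol synthesis, 0.064 for synaptic vesicles, 0.040 for oxidative phosphorylation, 0.077 for alcohol metabolism, -0.062 for immediate early genes and -0.016 for glutamate signalling. Without combination replicate 3 the list means were 0.20 for choroid plexus, 0.016 for oligodendrocyte precursors, 0.056 for astrocytes, -0.029 for pan-striatal neurons, -0.003 for D1-type neurons, 0.034 for sterol synthesis, 0.007 for synaptic vesicles, 0.023 for oxidative phosphorylation, 0.028 for alcohol metabolism, -0.055 for immediate early genes and -0.042 for glutamate signalling, and each call ended. Oligodendrocyte markers were called without any single array, but without combination replicate 3 their list mean was 0.050 (adjusted p = 0.0482), and without both arrays that stand apart the call ended (adjusted p = 0.0825). In addition, the endothelial call ended without mephedrone replicate 1 (-0.027) or combination replicate 2 (-0.035). Leaving out mephedrone replicate 1 also ended the calls of D1-type neurons (-0.099), synaptic vesicles (0.051) and glutamate signalling (-0.020). Mephedrone replicate 2 did so for alcohol metabolism (0.063), astrocytes (0.11), ependyma (0.062), oligodendrocyte precursors (0.095) and glutamate signalling (0.000), and mephedrone replicate 3 for immediate early genes (-0.028), astrocytes (0.11), oligodendrocyte precursors (0.066) and synaptic vesicles (0.049). Without combination replicate 1 immediate early genes (-0.056) and glutamate signalling (-0.005) lost their calls, as did glutamate signalling without ethanol replicate 1 (-0.016). Among means still called, choroid plexus had 1.19 without combination replicate 1. Without combination replicate 2 astrocytes had 0.18, D1-type neurons -0.17, synaptic vesicles 0.10 and glutamate signalling -0.002. Without mephedrone replicate 1 immediate early genes had -0.099, and without mephedrone replicate 3 glutamate signalling had -0.030.

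The ethanol main effect, 6 arrays against 6, had no probe set past the test in limma (0 of 28853, with 1516 at an unadjusted p under 0.05), and 1 without combination replicate 2. The rule for named genes took Gh alone, at -1.12 (SE 0.343, adjusted p = 0.898), not passed. Heat shock genes had a median of 0.070 with 23 of 25 above 0, sterol synthesis 0.071 with 15 of 15, oxidative phosphorylation 0.029 with 33 of 41 and astrocytes 0.089 with 13 of 14, led by Fgfr3 at 0.15, and these were called higher. Pan-striatal markers (-0.085) and ribosomal protein genes (-0.017) were called lower. No member of these 6 lists passed over all genes or adjusted over the list alone (adjusted p = 0.767 with an estimated correlation for each list). In all arrays the list means were 0.031 for oxidative phosphorylation, 0.079 for sterol synthesis, 0.11 for astrocytes, -0.086 for pan-striatal markers and -0.027 for ribosomal proteins. Without ethanol replicate 1 the list means of oxidative phosphorylation (0.012), sterol synthesis (0.051) and astrocytes (0.086) lost their calls. So did oxidative phosphorylation (0.022) and sterol synthesis (0.038) without combination replicate 3, and ribosomal proteins (-0.011) without ethanol replicate 3. Pan-striatal markers, still called, had -0.048 without ethanol replicate 1 and -0.031 without combination replicate 3, and without both arrays the list mean was 0.007 and the call ended (adjusted p = 0.966). Ribosomal proteins had -0.045 without ethanol replicate 1, still called.

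The interaction asked whether the combination departed from the sum of both single treatments, the question closest to the potentiation named in the series title. No probe set passed in limma (0 of 28853, with 991 at an unadjusted p under 0.05, fewer than the 1443 expected by chance). The smallest adjusted p, 0.786, was shared by C4b at 0.41 (SE 0.067) and Tek at -0.31 (SE 0.050). Dusp6, a phosphatase that limits ERK signalling, had -0.35 (SE 0.080), and neither it nor the others passed. Immediate early genes had a median of -0.24, with 21 of 27 below 0, none past the test over all genes and 1, Dusp6, lower adjusted over the list alone. Endothelial markers had a median of -0.10, with 12 of 13 below 0 and Tek lower adjusted over the list alone. The calls of these and the other lists were lost with an estimated correlation (adjusted p = 0.760 with an estimated correlation for all 9 called lists).

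The moderated F test for any difference among the 4 groups called 1 probe set, that of Ciart (adjusted p = 0.0170), with 2649 at an unadjusted p under 0.05. It called 6 without ethanol replicate 1 or saline replicate 1, 2 without combination replicate 2, and 0 without saline replicate 2 or 3, ethanol replicate 2 or 3, mephedrone replicate 2 or combination replicate 3. It called 0 with quantile normalisation or a replicate block, and 16 without both arrays that stand apart.

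Drd3, the dopamine D3 receptor gene named in the series title, passed in no comparison. Like those of Gh, Npas4, Gpx6, Fos and C4b, its probe set was not among those at a level of 8 or more. For ethanol against saline the SE of Drd3 was 0.255, where the median SE over all probe sets was 0.053. Its values were -0.054, -0.39 and -0.59 with saline, 0.34, 0.092 and 0.14 with ethanol, 0.052, -0.31 and 0.25 with mephedrone, and -0.001, 0.001 and -1.05 with the combination. The changes were 0.53 for ethanol against saline (SE 0.255, adjusted p = 0.995), 0.34 for mephedrone against saline (adjusted p = 0.853) and -0.006 for the combination against saline (adjusted p = 0.995). They were -0.35 for the combination against mephedrone (adjusted p = 0.988), -0.54 against ethanol (adjusted p = 0.511) and -0.88 for the interaction (SE 0.360, adjusted p = 1.00), with -0.098 and 0.092 (SE 0.180) for the main effects of mephedrone and ethanol. Adjusted over the dopamine list alone, the smallest of these p-values was 0.320, for the combination against ethanol. Without combination replicate 3 the change against saline was 0.34 and that against mephedrone 0.001. Over the 12 arrays Drd3 rose with the mean of the ventral forebrain markers (Pearson r = 0.82, permutation p = 0.00053, Spearman rho = 0.70, permutation p = 0.015, two-sided), and r was 0.71 without the 2 arrays farthest from the median of that mean. With each array taken as its deviation from its group mean, r was 0.80 (permutation p = 0.0012) and rho 0.78 (permutation p = 0.0044), and r was 0.81 without the 2 farthest arrays. Pearson p-values of the 3 relations computed were 0.0016, 0.0018 and 0.0087 after Benjamini-Hochberg adjustment, the last for the deviations without combination replicate 3 (r = 0.74).

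**Figure D4:**
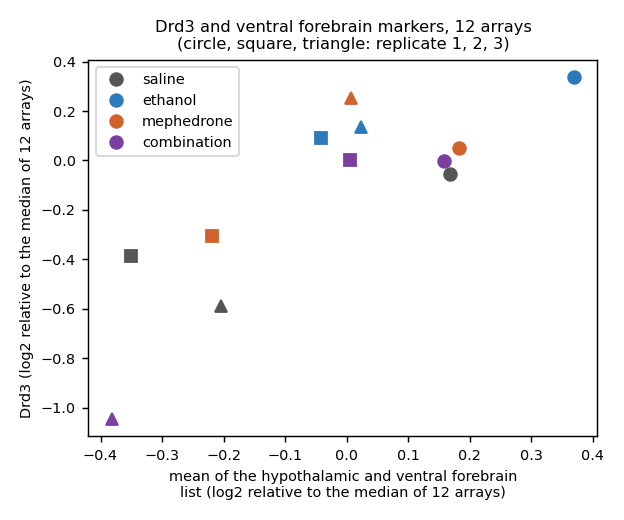
Drd3 level (vertical axis) against the mean of the hypothalamic and ventral forebrain marker list (horizontal axis), both in log2 relative to the median of 12 arrays. Points are the 12 arrays coloured by group, with shapes for the replicate number; combination replicate 3 lies lowest at -1.05.

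The responses to ethanol alone and to mephedrone alone, both against saline, correlated across probe sets at r = 0.45. Genes are not independent replicates, and both responses share the 3 saline arrays. In 100 simulations of unchanged groups sharing those arrays the mean r was 0.50, and the covariance was 0.00266 against 0.00305 simulated, so that the correlation did not exceed what shared controls give.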

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

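The test of a high ethanol group, and the values without both arrays that stand apart or with composition covariates, were chosen only after the results were seen. Each list below stands out because its ethanol effect differed between arrays with and without mephedrone by camera with a preset correlation; none did with an estimated correlation (adjusted p = 0.760 with an estimated correlation for all 9). Groups of 3 arrays were not tested for outlying arrays.

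Immediate early genes had a median interaction of -0.24 in log2. The median was -0.13 for heat shock and unfolded protein response genes, and 0.072 for sterol and fatty acid synthesis, where the list mean was 0.076 in all arrays, and -0.008 without combination replicate 3, 0.026 without ethanol replicate 2 and 0.061 without mephedrone replicate 3, all without a call. While called, it was 0.13 without ethanol replicate 1, 0.12 without combination replicate 2 and 0.049 without both arrays that stand apart. Cholinergic neuron markers had a median of -0.19 and a list mean of -0.31, with list means of -0.18 without combination replicate 3, -0.24 without saline replicate 2 and -0.30 without ethanol replicate 2, none called. Hypothalamic and ventral forebrain markers had a median of -0.25 and a list mean of -0.31, with list means of -0.15 without combination replicate 3, -0.18 without ethanol replicate 1, -0.20 without saline replicate 2 and -0.21 without mephedrone replicate 1, none called. Oligodendrocyte markers had 0.32 and endothelial markers -0.10, and both kept their calls when any single array was left out, but without combination replicate 3 the oligodendrocyte list mean was 0.13, against 0.33 in all arrays. Choroid plexus markers had a median of 0.77 and a list mean of 0.83, with list means of 0.28 without combination replicate 3 and 0.43 without saline replicate 2, neither called, and 1.28 without combination replicate 1, called. Ependymal markers had a median of 0.073 and a list mean of 0.088, with list means of 0.052 without saline replicate 2 and 0.062 without mephedrone replicate 2, neither called.

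Immediate early genes in arrays with mephedrone were weighed against 3 explanations, over the 18 members with an unadjusted p under 0.05 in the mephedrone main effect, of which 17 were lower, 1 (Nr4a2) was higher and 0 passed over all genes in limma. Cell composition, as the 2 scores measure it, did not account for most of the change in these 18 members. With 2 composition scores as covariates the median ratio of the changes to the unadjusted ones was 0.87 (quartiles 0.82 to 0.91). The first score was -1.93 to 0.56 with mephedrone and -0.84 to 0.65 without it. Scores that overlap so could take little from the changes, and composition that they do not hold stays open. Without both arrays that stand apart the median ratio was 0.94 (quartiles 0.87 to 1.02). The lowest was that of Npas4 at 0.45, with a change of -0.35 in all arrays and -0.16 without both. The members were chosen by their p in the same fit, so these ratios cover them alone. A high ethanol group in place of a low mephedrone group stays open, since the median ratio of the change against saline to that against ethanol was 0.47 (quartiles 0.21 to 0.67, median changes -0.17 and -0.33). Saline replicate 1, at 0.23, lay far above the other saline arrays at -0.080 and 0.008, so 3 saline arrays are too few to decide. An effect of mephedrone, of ethanol or of the interval between last dose, handling and dissection, which the labels do not give, remains possible and was not tested further.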

How the results depend on the processing

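The settings limited to a level of 8 or more, without both arrays that stand apart, and with composition covariates were chosen only after the data were seen; the others were planned. For the values below the cause was not tested, except that 1 value per symbol, a level limit and fewer arrays test fewer features or samples. The counts, in the order mephedrone against saline, combination against saline, combination against ethanol and mephedrone main effect, were 0, 1, 10 and 68. With quantile normalisation they were 3, 0, 0 and 45, with 0 for the F test. Centring each array gave 6 for the combination against ethanol. A trend and robust prior gave 4 for the combination against saline, none of them the main call of Ciart. It gave 3 for the combination against ethanol and 0 for the F test. Array quality weights gave 8 for mephedrone, 13 for the combination against saline, 350 for the mephedrone main effect and 23 for the F test. With a replicate block the combination had 0 against saline and 0 against ethanol, the mephedrone main effect 20 and the F test 0. One value per symbol gave 2, 5 and 23 for the combination against saline, against ethanol and the mephedrone main effect. An unadjusted p under 0.05 with a 1.5-fold change gave 6 for ethanol and 11 for mephedrone against saline, 70, 17 and 64 for the combination against saline, mephedrone and ethanol, 12 for the interaction, 37 and 2 for the main effects of mephedrone and ethanol, and for the F test without a fold limit 2649. Only the 6 arrays compared gave 1, 0 and 0 for the first 3 counts. A level of 8 or more gave 2 for mephedrone and 18 for the combination against saline. Without both arrays that stand apart the counts were 14, 12, 4 and 147, with 16 for the F test. Composition covariates gave 3 for the combination against saline and 0 against ethanol.

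Leaving out each array in turn gave 0 to 1 for ethanol against saline, 0 to 9 for mephedrone, 0 to 49 for the combination against saline, 0 to 1 against mephedrone and 0 to 17 against ethanol, 0 to 0 for the interaction, 10 to 114 for the mephedrone main effect, 0 to 1 for the ethanol main effect and 0 to 6 for the F test. Drd3 changes ranged from 0.41 to 0.68 for ethanol against saline, 0.22 to 0.49 for mephedrone, -0.18 to 0.34 for the combination against saline, -0.52 to 0.001 against mephedrone, -0.71 to -0.19 against ethanol, -1.05 to -0.53 for the interaction, and -0.19 to 0.077 and 0.005 to 0.27 for the main effects of mephedrone and ethanol. For the combination against saline Drd3 was 0.17 with quantile normalisation, 0.21 with array quality weights, 0.34 without both arrays that stand apart and 0.069 with composition covariates; for the mephedrone main effect it was 0.002, 0.025, 0.11 and 0.030. Without both arrays the change against mephedrone was 0.001. None passed.

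Of 77 list calls, all were lost with an estimated correlation, and over 1611 settings 1257 kept the call, 339 lost it and 15 turned the test's direction, without a call in it. The list means where it turned, several of which kept their sign, were 0.018 for immediate early genes with mephedrone against saline without saline replicate 1 (range without single arrays -0.137 to 0.018), and -0.021 for oligodendrocytes in the combination against ethanol without combination replicate 3 (range -0.021 to 0.271). Without both arrays that stand apart they were 0.092 (ventral forebrain) and -0.021 (oligodendrocytes) in the combination against ethanol, -0.027 (ventral forebrain) in the interaction, and 0.003 (oxidative phosphorylation) and 0.009 (sterol synthesis) in the ethanol main effect. With composition covariates, which remove such shifts by construction, they were 0.003 (ventral forebrain, ethanol against saline), 0.006 (synaptic vesicles) and 0.015 (oligodendrocyte precursors) against mephedrone, -0.031 (cortical), 0.042 (ventral forebrain) and 0.010 (choroid plexus) against ethanol, and -0.087 (cholinergic) and -0.018 (ventral forebrain) in the interaction. Means that changed sign while the test's direction held were 0.007 (pan-striatal, ethanol main effect) and 0.001 (ribosomal, mephedrone main effect) without both arrays, and -0.008 (sterol synthesis, interaction) without combination replicate 3 and with composition covariates, none called. The 31 gene results that passed kept their call in 324 of 617 settings, with 0 turned in sign; of the 106 that did not pass, 65 of 2092 settings gained a call. Planned filters on the lowest 30% and 50% by mean could not be run on a centred table. The replicate numbers gave no clear sign of pairing: the median correlation of same-numbered arrays was 0.007, against 0.002 for others. Same-numbered pairs ranged from -0.253 to 0.396, with 6 of 18 over 0.1, so pairing is not excluded. Signal over background is not in the table.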

Other observations

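The tests of clock phase and all 3 tests of Drd3, with the values without both arrays that stand apart or with composition covariates, were chosen only after the results were seen. Dopamine signalling genes, 20 measured, were called in no comparison, with a median of -0.050 in the mephedrone main effect. In it Maoa, which degrades monoamines, had 0.16 (SE 0.041) and was the 1 member past the test adjusted over the list alone (0 over all genes in limma). Neuropeptide and opioid genes, 19 measured and called in no comparison, had a median of 0.034, with Pdyn, the dynorphin precursor, at 0.17 (SE 0.057) and its receptor Oprk1 at 0.23 (SE 0.087), neither past a test. The other lists called in no comparison had medians in the mephedrone main effect of -0.011 for serotonin and noradrenaline signalling, -0.021 for GABA signalling, 0.005 for actin and dendritic spines, 0.023 for antioxidant genes, -0.017 for interferon genes, -0.021 for D2-type projection neurons, 0.000 for GABAergic interneurons, 0.002 for pericytes, 0.023 for neural precursors and -0.011 for blood cells.

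A set of 13 genes was weighed, the clock list members with an unadjusted p under 0.05 in the mephedrone main effect with Rbm3 and Cirbp, added after their values were seen; 5 passed over all genes in limma and 8 did not. Cell composition, as the 2 scores measure it, did not account for the changes in these 13 genes. The median ratio of adjusted to unadjusted changes was 0.98 after composition covariates (quartiles 0.95 to 1.02). The first score held 78.4% of the variance of the cell type list means. It was -1.93 to 0.56 with mephedrone and -0.84 to 0.65 without it. Scores that overlap so could take little from the changes, and composition that they do not hold stays open. Without both arrays that stand apart the median ratio was 0.97 (quartiles 0.92 to 1.06). In Ciart, Per3, Dbp, Arntl, Rbm3 and Nr1d2 the arrays with mephedrone did not overlap those without it. Leaving out 1 array of each side could therefore hardly lower their changes, so this ratio decides little. The genes were chosen by their values in the same fit, so these ratios cover them alone. A different clock phase at collection stays open: the 7 genes of the Dbp phase had a median of 0.23 and the 2 measured genes of the Arntl phase -0.26, a difference of 0.48, but genes that show the pattern cannot test its source. Among those not past the test over all genes, 4 remain for the Dbp phase and 1, Clock at -0.053, for the Arntl phase, too few to decide. The labels give no hour of collection, so the hour, the drug, or body temperature for Rbm3 cannot be told apart.

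The Drd3 level among arrays may follow the share of ventral forebrain tissue in the dissection, since deviations from group means of Drd3 and of that marker list correlated at r = 0.80 (permutation p = 0.0012). Drd3 was not compared with the other cell type lists, so the relation is not shown to be particular to this one. Combination replicate 3 alone is argued against, as r was 0.74 without it (permutation p = 0.0087). Of the 15 measured markers Nts and Trh are also in the neuropeptide list, and the centred table does not show which markers are abundant or how many the striatum itself expresses. Drug treatment cannot be told apart from no effect with 3 arrays per group, at an unadjusted F test p of 0.15.

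Other splits of the arrays were counted for each result in limma. For the mephedrone main effect, 100 of the 200 possible splits that kept the arrays of the other drug apart were drawn. Only the real one gave 68 probe sets, and the highest other gave 1, so such a count was rare among these splits. The splits take the arrays as independent, without a shared hour or batch, which the labels do not show, so chance is not excluded. For the F test 2 of 100 assignments gave at least 1 probe set, the real one included, with a highest other of 1. That share is under 0.05, but another assignment equalled the count of 1, which was 0 without several single arrays, so little rests on it. For the ethanol main effect and the interaction, with a real count of 0, all 100 of 100 gave as many, with highest others of 2 and 1. Any split reaches a count of 0, so this says nothing about chance. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real counts were 1 for the combination against saline and 10 against ethanol, each reached by 1 split with a highest other of 0. They were 0 for ethanol and mephedrone against saline and for the combination against mephedrone, each reached by 10 with a highest other of 0.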
